A study of Mus musculus with 12 samples.

How the data were processed

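Total RNA of mouse embryonic stem cells was sequenced as stranded TruSeq libraries, 12 in all, from cells grown on gelatin with serum and LIF in triplicate wells and purified with a Norgen single-cell kit. Groups were taken from the titles and the overexpression tag: Cas9 or Tnrc6a overexpression, each in control and in Trim71-/- cells, with 3 libraries per group. The free-text input lines of 9 libraries name other cells, so the grouping rests on titles, on the tag and, for Tnrc6a, on its RNA. Replicates are wells, and nothing in the labels gives a batch or a date.

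Per the labels, the authors used bcl2fastq 2.20 and STAR 2.7.3a with the mouse builds GRCm38 and mm10. The authors deposited raw counts per gene and library with no normalization, and these were the values used. The authors also deposited RPKM values, made per kilobase of a deposited gene length and per library size. In each library the RPKM values were the counts divided by that length and by 1 constant, which was 0.935 to 1.08 of the library's total. This fraction lay close to the library's factor by trimmed mean of M values computed here. It was 0.954 against 0.953 in Cas9 control replicate 1 and 1.078 against 1.077 in Tnrc6a control replicate 1. The deposited RPKM values thus appear to carry such a factor. The deposited gene length in bases is per the file headers of a type named quasr. The counting tool's settings, its annotation release and its strand setting are not given in the sources used here. The table listed 20529 genes, the lowest with 46 counts over the 12 libraries, so genes with fewer counts appear to have been left out before deposition. Symbols came from the table for 17158 genes and from the reference annotation (GENCODE M21, GRCm38) for 3357, and 14 genes had neither. In the reference, 20505 identifiers were found, and 54 symbols stood on at least 2 identifiers. Coordinates are from the same annotation.

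Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr by group, which kept 20486, libraries were scaled by trimmed mean of M values (TMM), and a quasi-likelihood model (glmQLFit, robust) with 1 mean per group was fitted to all 12 libraries. The comparisons were Trim71-/- against control with Cas9 and with Tnrc6a, Tnrc6a against Cas9 in control and in Trim71-/- cells, and the interaction. Tests were two-sided, and p values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Levels are CPM with TMM factors, given as mean ± SD of 3 libraries, and fold changes carry the standard error of the log2 value. A fold against a group with 0 counts is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts a ratio with its 95% interval is given. Intervals and floors cover counting error only, since reads carry no molecular identifiers.

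Before the data were examined, 22 gene lists were fixed and tested with limma's camera on log CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists within a comparison. The call was repeated with an estimated correlation. Camera compares a list with the other genes. Several lists share members, such as Cdkn1a in 3 of them. Named genes were also fixed by rule: the label genes, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap of the 6 libraries, 5 of each sign for the interaction, and up to 4 members per list. Predicted genes with placeholder names were skipped. The result of 1 gene is withheld and not reported here. Chromosome 8 and Ccr4 were singled out after their values were seen, and genes of at least 5 CPM were used for the chromosome medians.

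Genes were sorted by seed matches (8mer or 7mer to the eighth base) in the longest annotated 3' UTR for 5 microRNA families: let-7, the families of miR-290 and miR-302 and of miR-17, miR-20 and miR-106, and miR-122 and miR-1, which stem cells lack. This covered 14833 tested genes, while 5653 had no annotated 3' UTR and were left out.

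Alternatives were fixed beforehand: relative log expression and upper-quartile factors, no filter, a stricter filter (at least 1 CPM in 6 libraries), limma-voom, DESeq2, a 2-fold minimum, a block for the replicate number, a fit on the 2 groups compared only, an estimated correlation, 8mer sites only, and each library left out in turn. Added after the data were seen were tests without chromosome 8 genes, the gene lists with each library left out, and a seed background matched on UTR length (10 bins) and GC content (3 bins).

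Libraries were also regrouped in all 10 ways for each comparison of 3 against 3, and in 100 of 200 ways for the interaction. The latter was repeated, after its result was seen, with the average Tnrc6a log fold change of each gene as an offset in edgeR.

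The pipeline was tested on simulated data. Known changes were put into the counts of 50 genes per fold. For a comparison of 3 against 3, edgeR called 48% of genes changed 1.25-fold, 76% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. It made 12 false calls among 20286 unchanged genes. For the interaction it called 32%, 72%, 88% and 98%. Far fewer genes were changed than passed in the data, so these shares need not hold there. Scaling when most genes move was not tested. Camera gave a p under 0.05 to 2.5% of 200 random lists. Genes were simulated independently, so this does not test the preset correlation for lists whose members move together. For the 2-cell-like list that correlation was estimated at 0.165. The matched seed background reduced a difference of 0.0887, made by UTR length alone, to 0.00162.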

Results

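RNA was sequenced from mouse embryonic stem cells of the 129S6/SvEvTac background, which carried a reporter named GFP_5xT71BS and a stably transfected FLAG-Cas9 construct. The 12 libraries fell into 4 groups of 3, combining overexpression of Tnrc6a, or Cas9 alone, with a control genotype or cells labelled Trim71-/-. Trim71 is an RNA-binding protein of the TRIM-NHL family, and Tnrc6a (GW182) is the Argonaute partner that recruits deadenylases to silenced mRNAs. The series title places both in the question of whether distinct RNA-silencing routes meet on Tnrc6 proteins. Total counts per library ran from 20758151 to 27320667 in the Cas9 control group and from 23215587 to 31552915 in the Cas9 Trim71-/- group. They ran from 26022893 to 28372422 in the Tnrc6a control group and from 24303863 to 26467426 in the Tnrc6a Trim71-/- group. Of 20529 genes listed, 20486 were tested. The first principal component carried 63.4% of the variance and the second 16.8%.

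For 9 of the 12 libraries, a free-text line on the input RNA named other cells than the title did (HA-AVI-Tnrc6a, Ago2-/- or Upf1-/- cells), while titles and the overexpression tag gave the groups used here. Tnrc6a RNA separated the groups as titled. It stood at 132.2 ± 1.31 CPM (counts scaled to the library size; SD, n = 3) in the Cas9 control group and 3317 ± 120 in the Tnrc6a control group, a 25.1-fold difference. In the Trim71-/- groups it stood at 144.5 ± 9.79 and 3622 ± 126 CPM (log2 fold change 4.65, SE 0.04, edgeR adjusted p = 7.67e-48). Ago2 and Upf1 were not depleted in any group: Ago2 lay between 237.5 ± 15.3 and 331.6 ± 22.5 CPM, and Upf1 between 160.5 ± 5.27 and 241.8 ± 7.58 CPM. A knockout need not lower the RNA, as Trim71 below shows if the titles are right, so these levels do not exclude Ago2-/- or Upf1-/- cells.

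Trim71 RNA (chromosome 9, 114507133 to 114564369, GRCm38) was only slightly lower in the Trim71-/- libraries, so its level did not identify the genotype. It fell from 306.1 ± 14.2 to 275.2 ± 14.2 CPM (n = 3) with Cas9 (log2 fold change -0.15, SE 0.04, edgeR adjusted p = 0.00282). With Tnrc6a it fell from 264.2 ± 11.9 to 240.4 ± 9.13 CPM (log2 fold change -0.14, SE 0.04, edgeR adjusted p = 0.00758). Without Tnrc6a control replicate 3 this second call was lost (edgeR adjusted p = 0.0789). Ccr4, a chemokine receptor gene whose start lies 2216 bases downstream of the Trim71 end on the same strand, separated the genotypes completely. It rose from 0.706 ± 0.356 to 40.7 ± 0.868 CPM with Cas9 (log2 fold change 5.86, SE 0.14, edgeR adjusted p = 4.47e-32). With Tnrc6a it rose from 0.890 ± 0.0893 to 24.3 ± 1.54 CPM (log2 fold change 4.77, SE 0.14, edgeR adjusted p = 1.32e-29).

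**Figure D1:**
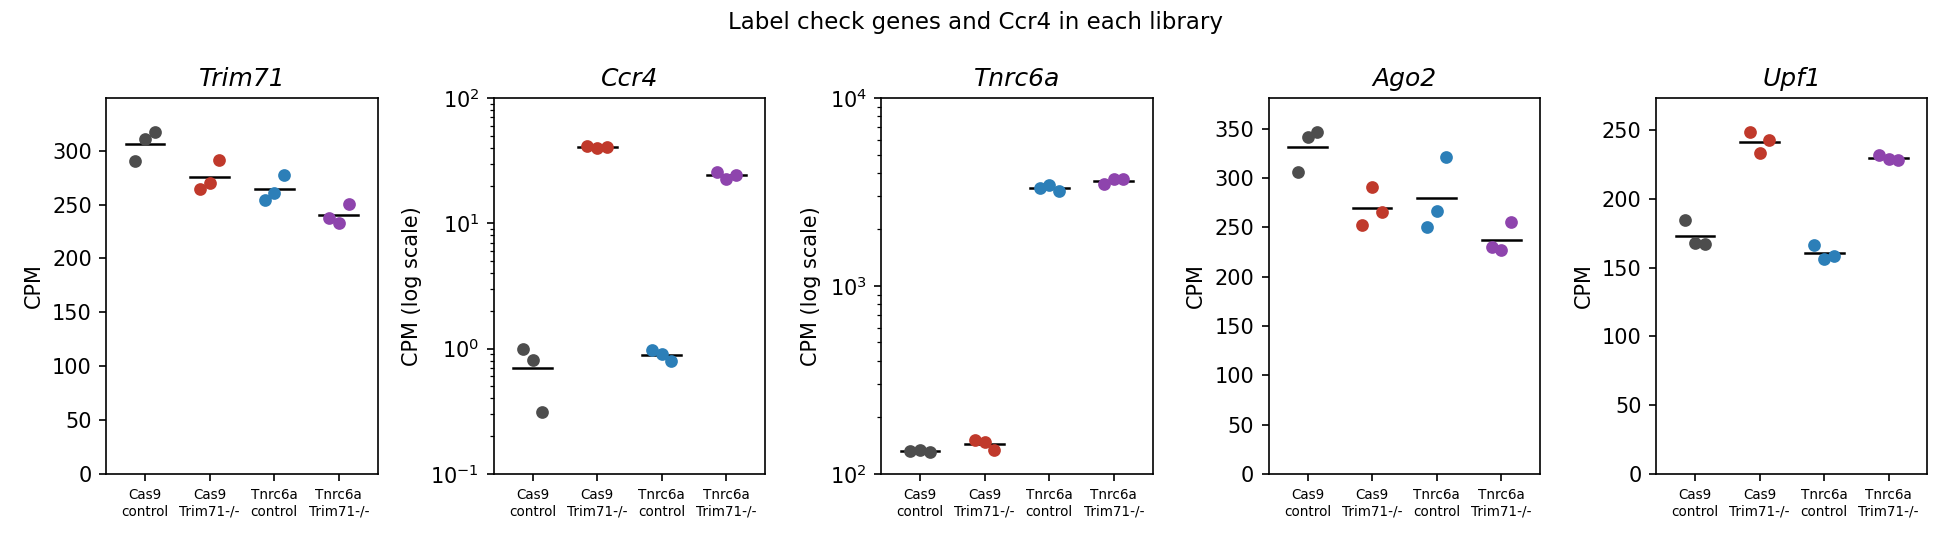
CPM of Trim71, Ccr4, Tnrc6a, Ago2 and Upf1 in each of the 12 libraries (points) with the group mean (bar, n = 3); the Ccr4 and Tnrc6a axes are logarithmic. Mean Ccr4 was 0.706 and 0.890 CPM in the control groups against 40.7 and 24.3 CPM in the Trim71-/- groups, and mean Tnrc6a was 3317 and 3622 CPM in the Tnrc6a groups.

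Genes on chromosome 8 were higher as a block in the Trim71-/- libraries. Over 664 genes of that chromosome with a mean of at least 5 CPM, the median log2 fold change was 0.49 with Cas9 (quartiles 0.31 and 0.63) and 0.52 with Tnrc6a (quartiles 0.32 and 0.65), a 1.41-fold and a 1.43-fold difference. Each of the 6 Trim71-/- libraries lay between 0.477 and 0.518 in its chromosome 8 median. The largest absolute median of any other autosome was 0.0695. Upf1, the helicase of nonsense-mediated decay, lies on this chromosome and rose by 0.48 with Cas9 (SE 0.04, edgeR adjusted p = 2.54e-13) and 0.52 with Tnrc6a (SE 0.04, edgeR adjusted p = 1.82e-14) on the log2 scale. Other chromosome 8 genes named in what follows are Zfp42, Irf2, Rbl2, Cnot1, Cnot7, Edc4, Msmo1, Mvd, Nkx6-3, Cpe, Sox1, Ttc29, Inpp4b and Nanos3.

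**Figure D2:**
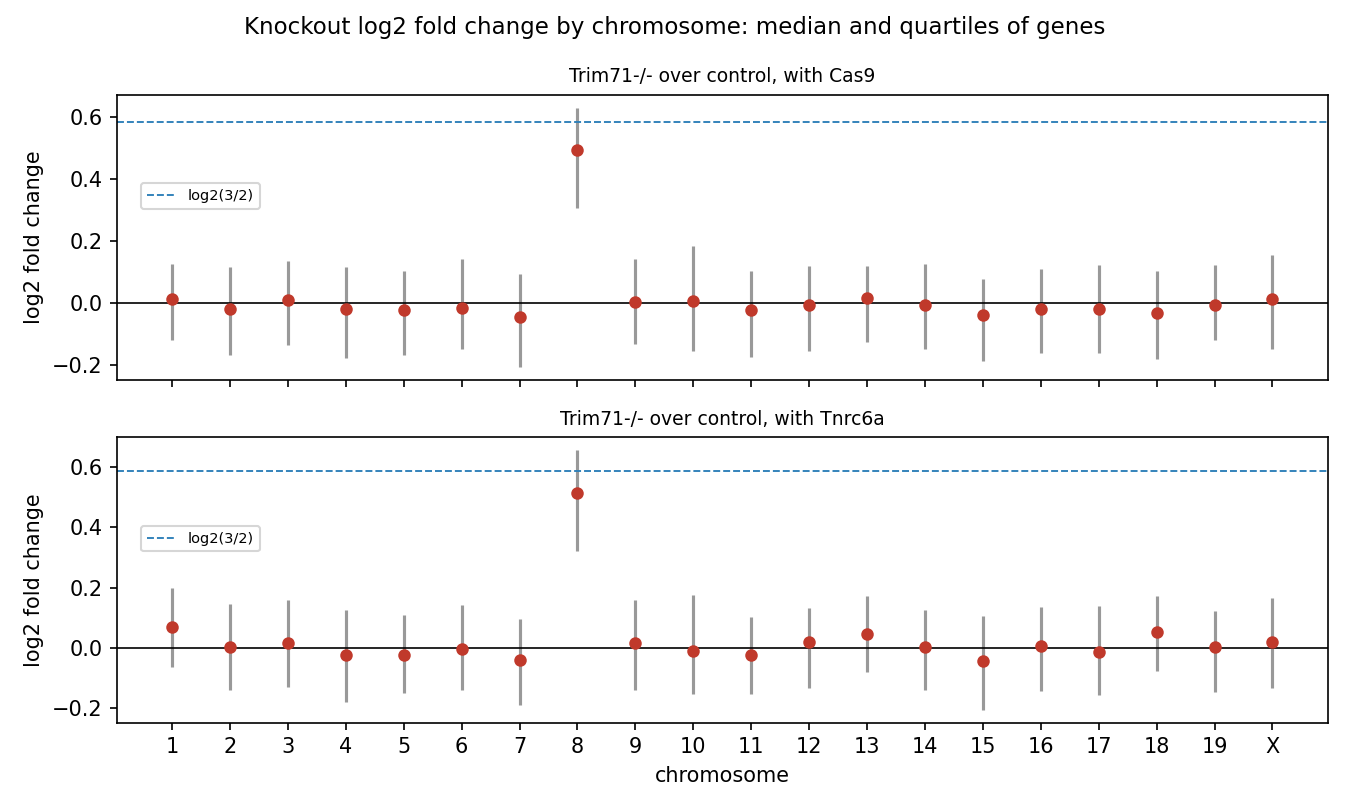
Median (points) and quartiles (lines) of the Trim71-/- log2 fold change of genes with a mean of at least 5 CPM, by chromosome, with Cas9 (top) and with Tnrc6a (bottom); the dashed line marks the log2 of a 3 to 2 ratio. Chromosome 8 stood at 0.49 and 0.52, and no other autosome had an absolute median above 0.0695.

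The first comparison asked what differed between Trim71-/- and control cells that carried Cas9 alone. All 16 tested genes of the 2-cell-like state, a rare state of stem cell cultures that resembles the early embryo, fell (median log2 fold change -3.09). Their summed level went from 39.95 ± 1.78 to 3.92 ± 0.941 CPM (SD, n = 3). Zscan4c fell 14.1-fold (log2 fold change -3.82, SE 0.17) and Zscan4d 12.9-fold (-3.69, SE 0.19), and Tmem92 fell too (-3.59, SE 0.49). Endoderm genes fell as a group: 15 of 17 were lower and 1 higher (median -1.62), among them Cubn (-4.47, SE 0.30) and the transcription factors Gata6 (-3.93, SE 0.14), Gata4 (-3.31, SE 0.11) and Sox17 (-2.96, SE 0.19). The camera adjusted p was 5.66e-14 for the 2-cell-like genes and 2.68e-12 for endoderm (0.0137 and 0.0094 with an estimated correlation). Without Cas9 Trim71-/- replicate 2 the Cubn value was -5.09. Counts come from reads of near-identical copies for the Zscan4, Tcstv and Usp17l families, so the share of each single copy is uncertain.

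Of 8 formative and primed pluripotency genes, 7 fell and 1 rose (median -0.94, camera adjusted p = 0.000284, or 0.0355 with an estimated correlation). Lef1, a mediator of Wnt signalling, fell most (log2 fold change -2.81, SE 0.34), and Pou3f1 (-1.51, SE 0.13) and the DNA methyltransferase Dnmt3a (-1.13, SE 0.05) fell too. Of 17 p53 target genes, 13 fell and 2 rose (median -0.39, camera adjusted p = 9.85e-07, or 0.0094 with an estimated correlation). The apoptosis gene Pmaip1 fell 3.91-fold (-1.97, SE 0.06), Sesn2 fell (-0.71, SE 0.04), and Perp rose (0.81, SE 0.06). Of 14 germ cell genes, 9 fell and 2 rose (median -0.46, camera adjusted p = 0.00381, or 0.0363 with an estimated correlation). The meiotic gene Stra8 fell 4.18-fold (-2.06, SE 0.10) and Sycp3 fell (-1.02, SE 0.14), while Prdm1 rose (1.07, SE 0.21).

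For 5 further lists the camera call was lost with an estimated correlation. Of 18 imprinted genes, 13 fell and 3 rose (camera adjusted p = 0.00222, and adjusted p = 0.0702 with an estimated correlation), among them Dlk1 (-1.70, SE 0.16), H19 (-2.39, SE 0.37; -3.04 without Cas9 Trim71-/- replicate 2) and Grb10 (-1.24, SE 0.04). Of 14 genes of the integrated stress response, 8 fell and 2 rose (camera adjusted p = 0.0067, and adjusted p = 0.167 with an estimated correlation), including its central factor Atf4 (-0.55, SE 0.04) and Atf3 (-0.73, SE 0.12). Of 20 glycolysis and hypoxia genes, 11 fell and 1 rose (camera adjusted p = 0.0067, and adjusted p = 0.119 with an estimated correlation), with Bnip3 (-0.85, SE 0.12) and Aldoa (-0.44, SE 0.03) lower. Of 4 Y-linked genes, 3 rose (camera adjusted p = 0.0067, and adjusted p = 0.119 with an estimated correlation), Kdm5d by 3.15 (SE 0.50). Of 20 naive pluripotency genes, 11 rose and 5 fell (camera adjusted p = 0.0499, and adjusted p = 0.167 with an estimated correlation), Zfp42 by 0.84 (SE 0.03) upward and Dppa5a downward (-0.84, SE 0.04). The naive call was also lost without chromosome 8 genes (camera adjusted p = 0.129), though the median hardly moved (0.0909 with them, 0.0877 without). It was lost too without Cas9 control replicate 3 (0.0898) or Cas9 Trim71-/- replicate 1 (0.0597), 2 (0.061) or 3 (0.0578).

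The other lists did not pass as groups. Of 7 reported TRIM71 mRNA targets, 4 rose and 2 fell (camera adjusted p = 0.0583, and 0.0371 without Cas9 control replicate 2). Mbnl1 (1.21, SE 0.08), Plxnb2 (0.90, SE 0.04) and the retinoblastoma-family gene Rbl1 (0.68, SE 0.06) were higher, and the immediate early gene Egr1 was 4.07-fold lower (-2.03, SE 0.08). Among 14 miR-290 and miR-302 targets, 3 rose and 7 fell (camera adjusted p = 0.124), with Dkk1 8.23-fold lower (-3.04, SE 0.35; -3.75 without Cas9 Trim71-/- replicate 2). Without chromosome 8 genes this list passed (camera adjusted p = 0.0133, and adjusted p = 0.0684 with an estimated correlation). Of 18 let-7 targets, 5 rose and 6 fell (camera adjusted p = 0.903), Lin28b upward (0.91, SE 0.07) and Lin28a downward (-0.69, SE 0.04). Counts were 3 up and 3 down of 13 for the small-RNA silencing machinery (camera adjusted p = 0.771), 3 up and 6 down of 23 for mRNA deadenylation and decay (0.883), and 5 up and 4 down of 16 for nonsense-mediated decay (0.922). The 3 decay genes that rose, Cnot1, Cnot7 and Edc4, lie on chromosome 8, as do Msmo1 and Mvd, the only risers among 18 cholesterol synthesis genes (2 up, 3 down, camera adjusted p = 0.847). Counts were 3 up and 4 down of 13 neural genes (camera adjusted p = 0.527), 0 up and 4 down of 11 streak and mesoderm genes (0.12), 1 up and 4 down of 8 trophoblast genes (0.124, and 0.0496 without Cas9 control replicate 2), and 1 up and 3 down of 7 fibroblast markers (0.771). The label genes as a list gave a camera adjusted p of 0.771, and for them and for the decay list the median and mean log2 fold change differed in sign. Adjusted over the list alone, counts equalled these except for endoderm (16 down), p53 targets (14 down), naive genes (13 up), glycolysis (2 up), trophoblast (5 down), silencing machinery (4 down) and label genes (2 up and 2 down against 2 and 1).

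Beyond the lists, the largest rises after Ccr4 included Xlr4a (log2 fold change 4.21, SE 0.25), Xlr3a (3.20, SE 0.16) and Xlr4c (2.90, SE 0.37) of a multicopy X-linked family, Zfp264 (4.21, SE 0.26), Ct55 (3.51, SE 0.37), Hus1b (3.41, SE 0.38; 4.15 without Cas9 control replicate 1), Nkx6-3 (3.24, SE 0.12) and Lemd1 (3.03, SE 0.24). Isg15, an interferon-stimulated gene with 0 counts in the control group, was at least 3.47-fold higher (floor of 3 counts over the group). The largest falls included Srgn, a proteoglycan core gene (-5.83, SE 0.26), and the transcription factor gene Foxq1 (-4.06, SE 0.20). Klb, the FGF co-receptor gene, had 3 counts in the Trim71-/- group and was 92.9-fold lower (95% counting interval 31.5 to 453). Ratios were 39.1 for Glipr1 (10.4 to 329), 42.2 for AF067061 (7.16 to 1710), 28.0 for Pramel18 (7.37 to 237), 20.6 for Pramel19 (5.33 to 176) and 24.3 for Spopfm1 (3.94 to 1000), all lower. Ankrd22 was at least 6.34-fold lower. Such ratios rest on few counts, and fitted log2 values moved with single libraries: Klb to -5.72 and Glipr1 to -4.42 without Cas9 Trim71-/- replicate 1, and to -7.26 and -7.77 without replicate 2. Pramel18 moved to -7.27 without replicate 1, AF067061 to -6.89 without replicate 2 and Spopfm1 to -6.12 without replicate 3 of that group, and Pramel19 to -3.41 without Cas9 control replicate 3. These genes, and those of largest change in the 3 comparisons that follow, were chosen so that the 3 libraries of one group did not overlap the 3 of the other. Chance gives this for 10% of genes, and being a rule of choice it adds no evidence. Among these genes of largest change, exons of Zfp264, Lemd1, Glipr1, Ankrd22, Foxq1 and Cubn, and later Pard3b, Sp110, Fcgr2b, Sox1 and Cphx2, overlap those of another annotated gene, and the strand setting of the counting is not given.

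In this comparison 7403 genes passed edgeR at an adjusted p of 0.05, 3495 higher and 3908 lower, of which 1077 differed at least 2-fold (371 higher, 706 lower). Without chromosome 8 genes, 6664 passed (2825 higher, 3839 lower), and a fit on these 2 groups alone gave slightly more higher than lower genes (3388 and 3368). Replicates were wells of cells, and each group was presumably 1 line, so the test measures spread between wells and line cannot be separated from genotype.

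The same genotypes were compared under Tnrc6a overexpression. The 16 genes of the 2-cell-like state fell again (median -1.50, camera adjusted p = 1.48e-10, or 0.0217 with an estimated correlation), from a summed 841 ± 20.2 to 306 ± 10.3 CPM (SD, n = 3), with Tmem92 5.39-fold lower (-2.43, SE 0.14) and Zfp352 3.17-fold lower (-1.66, SE 0.12). Of 17 endoderm genes, 16 fell (median -1.98, camera adjusted p = 9.51e-17, or 0.00622 with an estimated correlation). Cubn fell 131-fold (-7.03, SE 0.30), Sox17 10.7-fold (-3.42, SE 0.15), Gata4 7.32-fold (-2.87, SE 0.08) and Gata6 6.92-fold (-2.79, SE 0.09). All 8 trophoblast genes fell (median -1.09, camera adjusted p = 4.93e-06, or 0.0217 with an estimated correlation), including Hand1 (-2.20, SE 0.16), Cdx2 (-1.88, SE 0.29) and the keratin gene Krt18 (-1.33, SE 0.06). Of 14 germ cell genes, 12 fell and 1 rose (camera adjusted p = 4.93e-06, or 0.00878 with an estimated correlation), with Stra8 (-1.61, SE 0.08) and Mael (-1.12, SE 0.08) lower. Of 8 formative and primed genes, 7 fell (camera adjusted p = 9.13e-05, or 0.0217 with an estimated correlation), with Lef1 (-2.09, SE 0.33) and Pou3f1 (-1.39, SE 0.13) among them.

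For 6 lists under Tnrc6a the camera call was lost with an estimated correlation. Of 7 reported TRIM71 targets, 5 rose and 0 fell (camera adjusted p = 0.00398, and adjusted p = 0.0775 with an estimated correlation), led by Plxnb2 (1.14, SE 0.04), Mbnl1 (0.93, SE 0.08), Rbl2 (0.59, SE 0.09) and Rbl1 (0.55, SE 0.06). Of 20 naive pluripotency genes, 14 rose and 6 fell (camera adjusted p = 0.00141, and adjusted p = 0.061 with an estimated correlation), with Zfp42 (1.21, SE 0.03) and Esrrb (0.82, SE 0.03) higher and Dppa3 (-1.40, SE 0.35) lower. Of 14 stress response genes, 7 fell and 0 rose (camera adjusted p = 0.000945, and adjusted p = 0.098 with an estimated correlation), Atf4 by -0.52 (SE 0.04). Of 18 imprinted genes, 11 fell and 2 rose (camera adjusted p = 0.00141, and adjusted p = 0.061 with an estimated correlation), with Igf2 (-1.60, SE 0.09) and Dlk1 (-1.55, SE 0.16) lower. Of 20 glycolysis and hypoxia genes, 8 fell and 3 rose (camera adjusted p = 0.0446, and adjusted p = 0.193 with an estimated correlation), and all 4 Y-linked genes rose (camera adjusted p = 0.00285, and adjusted p = 0.0776 with an estimated correlation). One of these, Uty, was not called without any of 5 libraries (edgeR adjusted p from 0.0689 to 0.378): Tnrc6a control replicates 1 and 2 and the 3 Tnrc6a Trim71-/- replicates. Its call was lost too with relative log expression factors (edgeR adjusted p = 0.0702) and in DESeq2 (adjusted p = 0.1). The remaining lists did not pass (camera adjusted p from 0.175 to 0.962), p53 targets among them (3 up, 9 down, 0.175). Adjusted over the list alone, counts of the lists named here equalled these except for formative genes (1 up), TRIM71 targets (1 down) and imprinted genes (12 down).

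The largest rises under Tnrc6a were Ccr4, Zfp264 (4.34, SE 0.25), Nkx6-3 (3.6, SE 0.17), Hus1b (3.49, SE 0.35), Ct55 (3.46, SE 0.31), Xlr4a (3.43, SE 0.23), Cpe (3.08, SE 0.07), Xlr4c (3.08, SE 0.36), Xlr3a (3.06, SE 0.16) and Pard3b (3.03, SE 0.17). Without Tnrc6a control replicate 3 the values of Hus1b and Ct55 were 4.57 and 4.17. After Cubn, the largest falls were Srgn (-6.38, SE 0.20), Nostrin (-5.39, SE 0.39), Glipr1 (-5.03, SE 0.33), Klb (-4.92, SE 0.22), Foxq1 (-4.53, SE 0.14), Hkdc1 (-3.92, SE 0.34), Bmper (-3.79, SE 0.23), the retinol receptor gene Stra6 (-3.6, SE 0.32) and Tns4 (-3.56, SE 0.25). In all, 8005 genes passed edgeR (4104 higher, 3901 lower), 1157 of them at least 2-fold (471 higher, 686 lower). Without chromosome 8 genes, 7224 passed (3395 higher, 3829 lower). Lower genes were in the majority too with relative log expression factors (3577 higher, 4413 lower), upper-quartile factors (3926 and 4049) and DESeq2 (3297 and 4040). The same held without Tnrc6a control replicate 1 (3204 and 3822) or 2 (3149 and 3827) or Tnrc6a Trim71-/- replicate 2 (3139 and 3816), so the balance of directions is not settled.

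The knockout differences were largely shared between backgrounds: 2458 genes were higher in both, where independent lists would share 700, and 2393 were lower in both (744 by chance). Only 124 genes went opposite ways, against 1448 by chance (72 without Tnrc6a control replicate 1, and likewise without replicate 2). Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.659 and Spearman's rho 0.613. Without chromosome 8 genes, 1843 were higher and 2352 lower in both, and r was 0.648. Both Trim71-/- groups carry the chromosome 8 and Ccr4 differences, and line coincides with genotype in both comparisons. A difference between lines may thus be shared as well, so the overlap does not trace these genes to Trim71.

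Overexpression of Tnrc6a was next compared with Cas9 in control cells. The 16 genes of the 2-cell-like state all rose (median 4.32, camera adjusted p = 4.27e-11, or 0.0202 with an estimated correlation), from a summed 39.95 ± 1.78 to 841 ± 20.2 CPM (SD, n = 3). Zfp352 rose 34.8-fold (5.12, SE 0.20), Tcstv1 31.9-fold (5.00, SE 0.28) and Zscan4d 23.4-fold (4.55, SE 0.07). Of 8 trophoblast genes, 7 rose (median 2.18, camera adjusted p = 7.46e-05, or 0.0281 with an estimated correlation), with Hand1 17.0-fold (4.09, SE 0.20) and the keratins Krt7 (3.91, SE 0.29; 4.60 without Cas9 control replicate 1), Krt18 (3.68, SE 0.08) and Krt8 (3.08, SE 0.06) higher. Of 17 endoderm genes, 16 rose and 1 fell (median 1.08, camera adjusted p = 1.27e-05, or 0.0281 with an estimated correlation), with Foxa1 (1.69, SE 0.22), Foxa2 (1.64, SE 0.19) and Cubn (1.45, SE 0.16) higher. Without chromosome 8 genes the endoderm camera adjusted p with an estimated correlation was 0.0628, though the median hardly moved (1.03 without them). Of 14 germ cell genes, 12 rose (median 0.83, camera adjusted p = 2.71e-05, or 0.0184 with an estimated correlation), including Taf7l (2.33, SE 0.09) and the germline helicase gene Ddx4 (1.29, SE 0.05). Of 17 p53 targets, 12 rose and 3 fell (median 0.51, camera adjusted p = 0.000222, or 0.0197 with an estimated correlation), with Plk2 (1.52, SE 0.04), Btg2 (1.51, SE 0.04) and the cell-cycle inhibitor Cdkn1a (1.47, SE 0.05) higher.

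Genes of the naive pluripotent state fell with Tnrc6a in control cells: 17 of 20 were lower and 3 higher (median -0.61, camera adjusted p = 5.35e-05, or 0.0261 with an estimated correlation). Tcl1 (-1.32, SE 0.07), the Nodal co-receptor gene Tdgf1 (-1.31, SE 0.03) and Nr0b1 (-1.17, SE 0.04) fell, while Dppa3 rose (1.92, SE 0.38). Of 18 cholesterol synthesis genes, 16 fell and 1 rose (median -0.37, camera adjusted p = 7.46e-05, or 0.0184 with an estimated correlation), with Idi1 (-0.84, SE 0.06) and Cyp51 (-0.65, SE 0.05) lower. Of 18 let-7 targets, 13 fell and 2 rose (median -0.37, camera adjusted p = 0.000409, and adjusted p = 0.0629 with an estimated correlation). Myc (-1.53, SE 0.05), Lin28a (-1.45, SE 0.04) and the cyclin genes Ccnd1 (-1.44, SE 0.04) and Ccnd2 (-1.42, SE 0.11) fell. The other lists did not pass (camera adjusted p from 0.0512 to 0.956). Among them, formative genes (4 of 8 lower, 0.0512) passed without Cas9 control replicate 1 (0.0274) or Tnrc6a control replicate 3 (0.0486). The stress response list (8 up, 3 down, 0.0711) passed without Cas9 control replicate 1 (camera adjusted p = 0.0382), and its members Ddit4 (2.18, SE 0.06), Atf3 (1.85, SE 0.10) and Ddit3 (1.73, SE 0.09) rose. In the silencing machinery (4 up, 6 down of 13, camera adjusted p = 0.528), Ago4 rose (1.68, SE 0.26) and Ago1 fell (-0.73, SE 0.05). Adjusted over the list alone, counts of these lists were equal, except for the silencing machinery (7 down).

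Other large rises with Tnrc6a in control cells were Sp110 (5.50, SE 0.16), Cpb2 (5.42, SE 0.38), the guanylate-binding protein gene Gbp2b (5.41, SE 0.27), Tdpoz4 (5.28, SE 0.29) and the neurokinin receptor gene Tacr3 (5.17, SE 0.45). Isg15 was at least 19-fold higher, and ratios to 1 to 3 control counts were 215 for Spz1 (95% counting interval 38.2 to 8521), 124 for D13Ertd608e (42.1 to 602) and 50.0 for Irf2 (13.5 to 418). Control libraries moved some of these: without Cas9 control replicate 1 the log2 value was 9.13 for Tacr3 and 7.61 for D13Ertd608e, and without replicate 2 it was 9.33 for Spz1. Without replicate 3 it was 4.56 for Tacr3, 6.01 for Gbp2b and 5.94 for Tdpoz4. The largest falls were smaller: Fcgr2b (-2.95, SE 0.29), Platr6 (-2.67, SE 0.30), Fgf17 (-2.53, SE 0.11), Nlrp4a (-2.45, SE 0.32), Insyn2b (-2.44, SE 0.22), Ttc29 (-2.40, SE 0.36), the neural gene Sox1 (-2.34, SE 0.16), Myo1f (-2.32, SE 0.10), Nsg2 (-2.29, SE 0.20) and the hormone precursor gene Trh (-2.27, SE 0.06). In all, 13007 genes passed edgeR, 6230 higher and 6777 lower, while among the 2911 with at least a 2-fold difference 2254 were higher and 657 lower. The majority among all called genes turned with relative log expression factors (6759 higher, 6153 lower), upper-quartile factors (6604 and 6318), DESeq2 (6435 and 5898) and a fit on the 2 groups alone (6502 and 6465). It also turned without Tnrc6a control replicate 1 (6148 and 6031) or 2 (6114 and 5980). The Tnrc6a and Cas9 groups were separate cell populations, so differences between populations other than Tnrc6a count in this comparison too.

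In Trim71-/- cells, Tnrc6a overexpression went with a rise of the same 16 genes of the 2-cell-like state (median 5.88, camera adjusted p = 5.98e-12, or 0.0163 with an estimated correlation), from a summed 3.92 ± 0.941 to 306 ± 10.3 CPM (SD, n = 3). Zscan4d rose 133-fold (7.06, SE 0.12), Zscan4c 114-fold (6.83, SE 0.12) and Zscan4f 94.3-fold (6.56, SE 0.10). Of 17 p53 targets, 14 rose and 1 fell (median 0.98, camera adjusted p = 1.43e-07, or 0.00619 with an estimated correlation), with the death receptor gene Fas (2.39, SE 0.44), Plk2 (1.95, SE 0.04) and Cdkn1a (1.80, SE 0.05) higher. Of 14 germ cell genes, 12 rose and 1 fell (camera adjusted p = 0.00021, or 0.0163 with an estimated correlation), Taf7l by 2.16 (SE 0.09). Of 18 cholesterol synthesis genes, 16 fell and 1 rose (camera adjusted p = 8.89e-05, or 0.0163 with an estimated correlation), with Cyp51 (-0.58, SE 0.05) lower. Of 18 let-7 targets, 15 fell and 2 rose (median -0.51, camera adjusted p = 2.15e-05, or 0.0375 with an estimated correlation), with Ccnd2 (-2.10, SE 0.11), Lin28a (-1.67, SE 0.04), Ccnd1 (-1.62, SE 0.04) and Myc (-1.51, SE 0.06) lower.

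For 6 more lists in Trim71-/- cells the call was lost with an estimated correlation. Of 8 trophoblast genes, 5 rose (median 1.34, camera adjusted p = 0.00309, and adjusted p = 0.0744 with an estimated correlation), Hand1 by 2.85 (SE 0.29) and Krt18 by 2.68 (SE 0.09). Of 17 endoderm genes, 12 rose and 2 fell (camera adjusted p = 0.0109, and adjusted p = 0.168 with an estimated correlation), with Gata6 (2.42, SE 0.17) and Gata4 (1.62, SE 0.14) higher. Of 20 naive genes, 14 fell and 3 rose (camera adjusted p = 0.00291, and adjusted p = 0.0744 with an estimated correlation), with Utf1 (-1.10, SE 0.04) and Tdgf1 (-0.94, SE 0.03) lower. Of 14 miR-290 and miR-302 targets, 8 rose and 2 fell (camera adjusted p = 0.0244, and adjusted p = 0.0744 with an estimated correlation), with Irf2 (3.68, SE 0.34), Tgfbr2 (2.39, SE 0.17) and Lats2 (1.73, SE 0.09) higher. Of 8 formative genes, 6 fell (camera adjusted p = 0.0194, and adjusted p = 0.106 with an estimated correlation), and of 20 glycolysis and hypoxia genes 12 fell and 5 rose (camera adjusted p = 0.0493, and adjusted p = 0.198 with an estimated correlation). Without chromosome 8 genes the naive list passed with an estimated correlation too (camera adjusted p = 0.0485), while the endoderm and miR-290 and miR-302 lists (each camera adjusted p = 0.0616) and the glycolysis list (0.0802) did not pass with the preset one. Their medians without these genes were 0.65, 0.29 and -0.20, against 0.68, 0.29 and -0.25 with them, so the lost calls do not show that chromosome 8 genes carried the shifts. The glycolysis list did not pass either without Cas9 Trim71-/- replicate 3 (0.0718) or Tnrc6a Trim71-/- replicate 1 (0.0579) or 2 (0.0551). The remaining lists did not pass (camera adjusted p from 0.104 to 0.825), and adjusted over the list alone, counts of the lists named here were equal.

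The largest rises in Trim71-/- cells included genes with at most 2 counts in the Cas9 group: D13Ertd608e was at least 55.6-fold and Ankrd22 at least 46.8-fold higher. Ratios were 254 for AF067061 (95% counting interval 45.1 to 10057), 225 for Spopfm1 (40.1 to 8940), 218 for the phosphatase gene Inpp4b (38.7 to 8642), 161 for the netrin receptor gene Dcc (44.3 to 1337) and 131 for Tcstv1 (23.1 to 5215). Single Cas9 libraries moved these ratios: fitted log2 values were 9.22 for Inpp4b and 8.49 for Tcstv1 without Cas9 Trim71-/- replicate 1, 9.47 for AF067061 without replicate 2 and 9.31 for Spopfm1 without replicate 3. The largest falls were Insyn2b (-2.81, SE 0.22), Foxr2 (-2.74, SE 0.29), Ms4a14 (-2.66, SE 0.40; -3.77 without Tnrc6a Trim71-/- replicate 1), Platr26 (-2.51, SE 0.22), Cphx2 (-2.30, SE 0.41), Cd59b (-2.26, SE 0.23), Platr3 (-2.23, SE 0.23), Fcgr2b (-2.21, SE 0.24), Pdyn (-2.17, SE 0.25) and Myo1f (-2.15, SE 0.09). In all, 12884 genes passed edgeR (6562 higher, 6322 lower), 2954 of them at least 2-fold (2366 higher, 588 lower), and without Tnrc6a Trim71-/- replicate 2 the majority of all called genes turned (6023 higher, 6132 lower). Between genotypes, 5216 genes were higher with Tnrc6a in both (1996 by chance), 5456 lower in both (2091 by chance) and 82 opposite (4093 by chance; 52 or 54 without Tnrc6a control replicate 1 or 2). Across genes, Pearson's r was 0.879 and Spearman's rho 0.850.

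**Figure D3:**
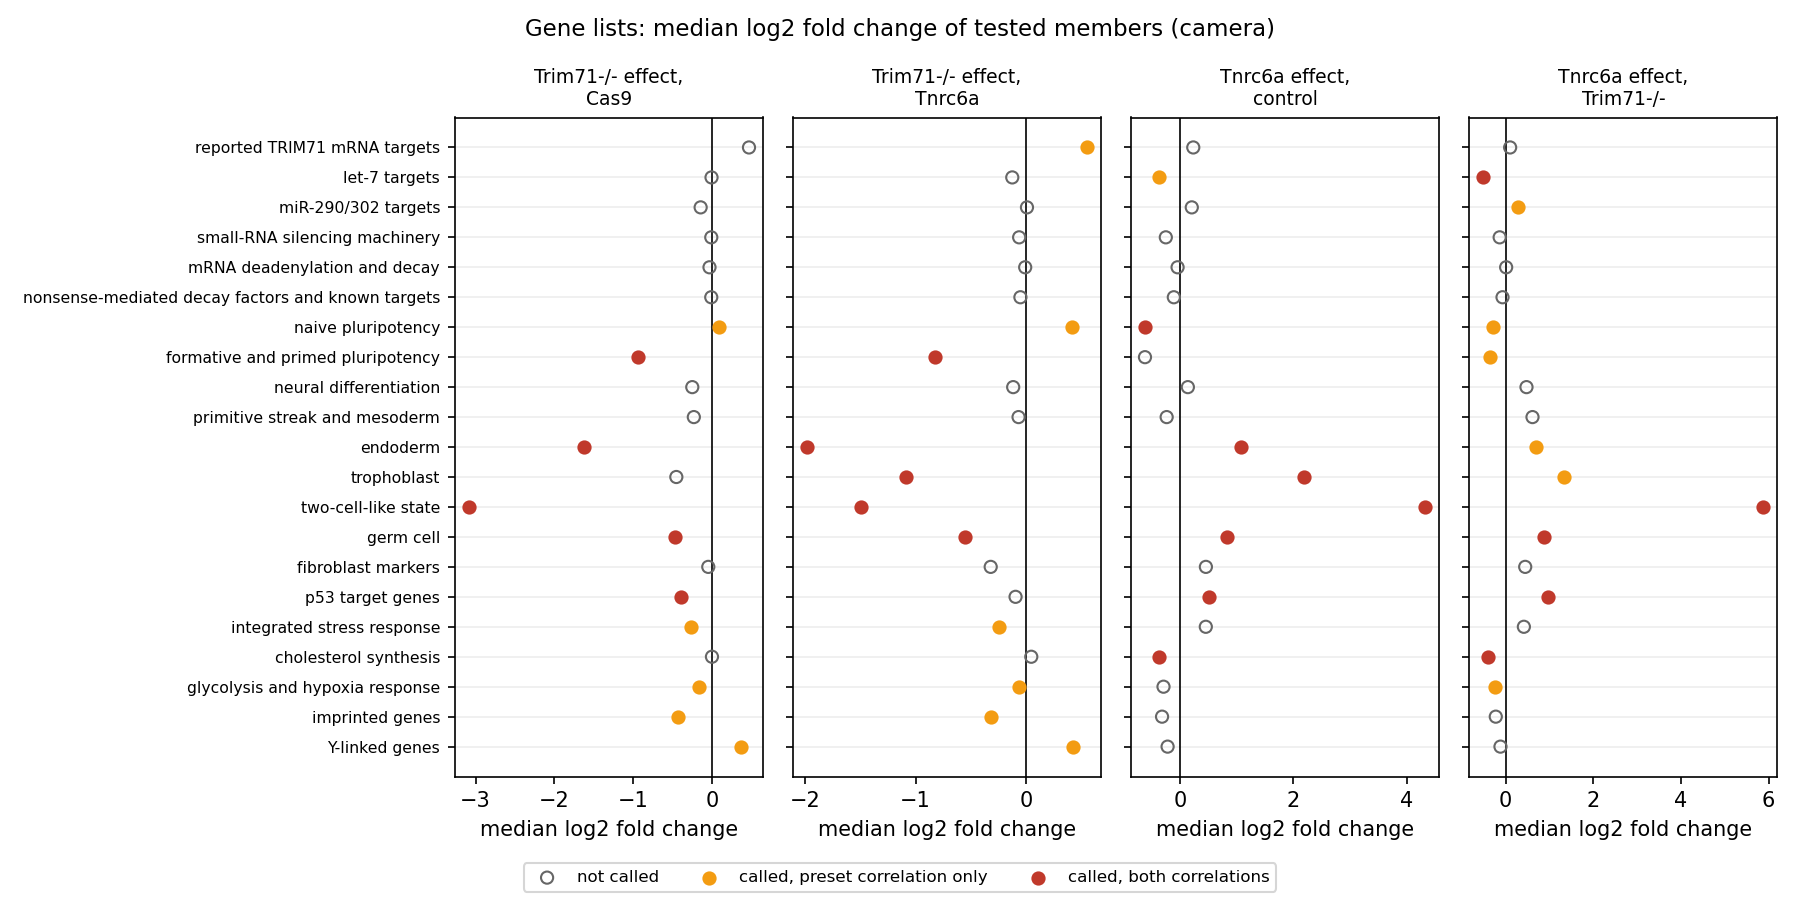
Median log2 fold change of the tested members of 21 gene lists in the 4 comparisons of 3 against 3 libraries; open points did not pass camera, orange points passed with the preset correlation only and red points with both. The 2-cell-like list stood farthest from 0 in 3 panels, at -3.09, 4.32 and 5.88, and the endoderm list in the Trim71-/- comparison with Tnrc6a, at -1.98.

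**Figure D4:**
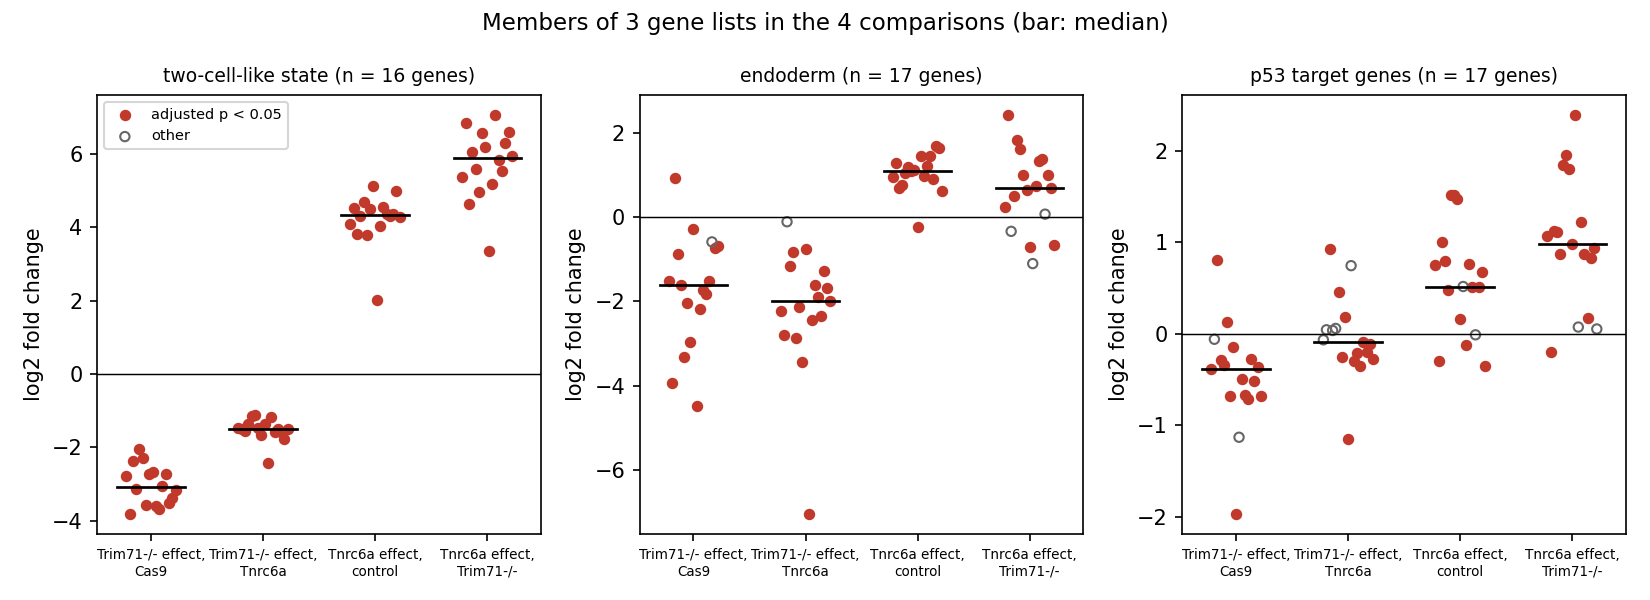
Log2 fold change of each tested member (points, filled where the edgeR adjusted p was under 0.05) and the median (bar) for 3 lists in the 4 comparisons. All 16 genes of the 2-cell-like state were lower in both Trim71-/- comparisons and higher in both Tnrc6a comparisons.

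Whether the Trim71-/- difference depended on Tnrc6a was tested as the interaction, the Trim71-/- log2 fold change with Tnrc6a minus that with Cas9. All of the 14 p53 targets that passed, of 17, had a positive interaction (median 0.32, camera adjusted p = 8.89e-14, or 0.000638 with an estimated correlation): Pmaip1 (0.82, SE 0.08), Trp53inp1 (0.46, SE 0.06) and Plk2 (0.43, SE 0.06) were less reduced in Trim71-/- cells when Tnrc6a was overexpressed. Of 16 genes of the 2-cell-like state, 8 had a positive interaction that passed edgeR (median 1.40, camera adjusted p = 3.71e-09, or 0.0376 with an estimated correlation), Zscan4c by 2.31 (SE 0.20), Zscan4f by 2.08 (SE 0.18) and Zscan4e by 1.94 (SE 0.23). Trophoblast genes had a negative one (median -0.96, camera adjusted p = 3.04e-06, or 0.0342 with an estimated correlation), with Krt8 (-1.21, SE 0.09) and Krt18 (-1.0, SE 0.13) past the gene threshold among 8. Of 20 naive genes, 11 had a positive and 2 a negative interaction (median 0.26, camera adjusted p = 6.69e-05, or 0.0376 with an estimated correlation), including Esrrb (0.50, SE 0.05), Zfp42 (0.37, SE 0.05) and Tdgf1 (0.36, SE 0.05).

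Endoderm genes had a negative median interaction (-0.46, camera adjusted p = 0.0001, and adjusted p = 0.0646 with an estimated correlation): of 17, 5 were negative, such as Sox7 (-1.29, SE 0.23) and Lamb1 (-0.71, SE 0.07), and Gata6 was positive (1.14, SE 0.20). Of 14 miR-290 and miR-302 targets, 5 were positive (median 0.11, camera adjusted p = 0.0186, and adjusted p = 0.0646 with an estimated correlation), including Lats2 (0.65, SE 0.12) and Ei24 (0.41, SE 0.06); without Cas9 control replicate 2 this call was lost (camera adjusted p = 0.0569), and without chromosome 8 genes it was kept with an estimated correlation (adjusted p = 0.0494). The let-7 list did not pass (1 positive, 4 negative of 18, camera adjusted p = 0.0854), but it passed without Cas9 control replicate 3 (0.0381), Tnrc6a control replicate 1 (0.0235) or 2 (0.0196) or Tnrc6a Trim71-/- replicate 1 (0.046), and with relative log expression factors (0.0488). Egr1, lower in Trim71-/- cells with Cas9, had an interaction of 1.84 (SE 0.12, edgeR adjusted p = 9.58e-13), and Igf2 one of -1.25 (SE 0.15, edgeR adjusted p = 6.92e-08). The remaining lists did not pass (camera adjusted p from 0.191 to 0.979). Adjusted over the list alone, counts were 15 positive p53 targets, 10 positive genes of the 2-cell-like state, 5 negative trophoblast genes, 2 positive and 8 negative endoderm genes, and 2 positive and 5 negative let-7 targets, with the other lists named here equal.

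In all, 1419 genes had an interaction that passed edgeR, 958 positive and 461 negative, 179 of them at least 2-fold (125 positive, 54 negative). With relative log expression factors the positive ones numbered 768 and the negative ones 613. Without Tnrc6a control replicate 1 or 2 or Tnrc6a Trim71-/- replicate 2 they numbered 548, 543 and 584, beside 511, 519 and 521 negative ones. Among genes of at least 5 CPM, chromosome 1 held 92 positive and 15 negative ones (median interaction 0.0678), and chromosome 18 held 52 and 11 (0.0515). Chromosomes 16 (27 and 4, median interaction 0.0151) and 7 (64 and 21, 0.00974) were one-sided too. The balance was closer on chromosomes 4 (51 and 35) and 11 (54 and 36). Each group was presumably 1 line, so differences between lines cannot be separated from the interaction. For the 4836 genes higher on average in Trim71-/- cells the median interaction was 0.0247 (camera p = 0.415, or p = 0.159 with an estimated correlation), and for the 4993 lower genes it was 0.0346 (camera p = 0.581, or p = 0.342 with an estimated correlation). Over all tested genes the median interaction was 0.0213. Without Cas9 control replicate 3 the lower genes had a median of 0.0454 (camera p = 0.216, or p = 0.0238 with an estimated correlation). With all libraries, the overall size of the Trim71-/- response was not shown to differ between backgrounds.

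Genes with a microRNA seed match in the annotated 3' UTR were compared with genes lacking one, over 14833 genes, since Tnrc6a acts in microRNA silencing. In Trim71-/- cells, genes with miR-17, miR-20 and miR-106 matches were slightly higher with Tnrc6a than genes without (difference of medians 0.117, camera adjusted p = 0.0444, and adjusted p = 0.297 with an estimated correlation). The call was not kept against genes matched on UTR length and GC content (0.0677, camera adjusted p = 0.250). For 8mer matches alone the difference was 0.172 (camera adjusted p = 0.00373, and adjusted p = 0.278 with an estimated correlation). All tests of 8mer matches used the unmatched background, and for this one the median UTR was 2691.5 against 971 bases. In control cells the miR-17, miR-20 and miR-106 difference was 0.10 (camera p = 0.0488, adjusted p = 0.244), and that for 8mer matches alone passed (0.138, camera adjusted p = 0.0253, and adjusted p = 0.417 with an estimated correlation). Genes with miR-290 and miR-302 matches differed by 0.0883 in Trim71-/- cells (camera adjusted p = 0.0588, and 0.0286 for 8mer matches, or adjusted p = 0.278 with an estimated correlation) and by 0.0774 in control cells (camera adjusted p = 0.293). Genes with let-7 matches differed by 0.0589 and 0.0712, miR-122 by 0.0244 and 0.0171 and miR-1 by 0.0435 and 0.0290 in the same order, none passing. Genes with miR-290 and miR-302 matches had longer 3' UTRs (median 2472 against 933 bases). In the Trim71-/- comparisons 0 of 5 families passed camera, and 0 had an unadjusted p under 0.05 (lowest adjusted p 0.847 with Cas9 and 0.994 with Tnrc6a).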

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

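The tests of chromosome 8 and of Ccr4, the relabelling test with the Tnrc6a difference held fixed, and the settings without chromosome 8 genes or with single libraries left out for lists, were chosen only after the results were seen. The other tests were planned.

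The Trim71-/- difference was not the same with Tnrc6a as with Cas9 for 1419 genes by the edgeR interaction test, which is why these results are set apart. Exchanging Cas9 and Tnrc6a labels within each genotype gave at least as many genes in 6 of 100 splits (drawn from 200, the real one included). The highest other split called 14872 genes, several times the real 1419, which points to a structure of the samples. An exchange in 1 genotype moves the Tnrc6a difference itself into the interaction, so this count decides nothing about chance. With the average Tnrc6a difference of each gene held fixed, 1 of the same 100 splits, the real one, called 1419 genes and the highest other 22. That difference was estimated with the real labels. The count argues at 0.05 against a chance exchange of wells only. Each group was presumably 1 line, so chance differences between lines are not excluded. Among the lists, the median interaction was 0.324 for p53 targets, 1.40 for the 2-cell-like state, -0.957 for trophoblast, 0.261 for naive pluripotency, -0.461 for endoderm and 0.114 for miR-290 and miR-302 targets. With an estimated correlation the camera adjusted p was 0.0646 for the last pair, endoderm and miR-290 and miR-302 targets, and without Cas9 control replicate 2 the miR-290 and miR-302 call was lost too (0.0569). That list passed, without chromosome 8 genes, with an estimated correlation (camera adjusted p = 0.0494).

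Single genes differed as well, by the same interaction test. Zscan4d (2.51, SE 0.21, edgeR adjusted p = 1.43e-11), the phosphatase gene Inpp4b (3.81, SE 0.92, edgeR adjusted p = 0.00592) and Pramel7 (-1.56, SE 0.40, edgeR adjusted p = 0.0107) kept their calls with each single library left out. Ankrd22 (4.45, SE 1.29, edgeR adjusted p = 0.0269) lost its call without Cas9 control replicate 1 or any of the 3 Cas9 Trim71-/- replicates (0.062 to 0.0936). AF067061 (3.14, SE 0.88, edgeR adjusted p = 0.0206) lost it without Cas9 control replicate 3 or Cas9 Trim71-/- replicate 1 or 3, and in DESeq2 (0.0579 to 0.121). Spopfm1 (3.03, SE 0.91, edgeR adjusted p = 0.0325) lost it without Cas9 control replicate 2, Cas9 Trim71-/- replicate 1 or 2, Tnrc6a control replicate 2 or Tnrc6a Trim71-/- replicate 2, and in DESeq2 (0.0543 to 0.155). Nostrin (-2.54, SE 0.80, edgeR adjusted p = 0.045) lost it without Cas9 control replicate 2, Cas9 Trim71-/- replicate 3, Tnrc6a control replicate 1 or 2 or any Tnrc6a Trim71-/- replicate, and in limma-voom (0.0525 to 0.44). Adamts3 (-1.79, SE 0.49, edgeR adjusted p = 0.0181) lost it without Cas9 control replicate 1, Cas9 Trim71-/- replicate 2 or Tnrc6a Trim71-/- replicate 2 (0.0522 to 0.0971). Sp5 (-1.52, SE 0.45, edgeR adjusted p = 0.0283) lost it without Cas9 control replicate 3, Cas9 Trim71-/- replicate 1 or Tnrc6a Trim71-/- replicate 3 (0.0763 to 0.175). Nanos3 (-1.40, SE 0.42, edgeR adjusted p = 0.0299) lost it without Cas9 control replicate 1, Cas9 Trim71-/- replicate 1, Tnrc6a control replicate 2 or 3 or Tnrc6a Trim71-/- replicate 2 (0.0564 to 0.103). Ankrd22, AF067061, Spopfm1 and Inpp4b had at most 1 count in the Cas9 Trim71-/- group, so their fitted interaction depends on the prior count. Some values moved with single Cas9 Trim71-/- libraries: Inpp4b to 5.70 without replicate 1, AF067061 to 5.07 without replicate 2, Spopfm1 to 4.97 without replicate 3, and likewise Nostrin to -1.60 without replicate 3.

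Chromosome 8 genes were higher in both Trim71-/- groups. Library scaling is argued against, because the largest absolute median of another autosome was 0.0695, and so are single genes that answer to the loss of Trim71, because at least 83.1% of chromosome 8 genes lay above 0.2. An extra copy of chromosome 8 in the Trim71-/- line is a candidate explanation, though DNA was not measured. Among 10-Mb stretches with at least 20 genes the lowest median was 0.416 and the highest 0.598 (0.643 with Tnrc6a in a stretch of 11 genes). The chromosome 8 values were known when this test was chosen, so it cannot decide whether a copy is present. The chromosome medians, 1.41-fold with Cas9 and 1.43-fold with Tnrc6a, fell short of the 3 to 2 ratio of an extra copy. Whether such a copy, if present, arose by chance in a line or goes with the loss of Trim71 stays open, since line and genotype coincide.

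Ccr4 was higher in both Trim71-/- groups, while Trim71 RNA was little changed. A change of a wider stretch is argued against, because the 10 other genes of at least 5 CPM within 500 kb moved by at most 0.534 on the log2 scale, though 2 weaker ones rose more, Cmtm8 with Cas9 (0.89) and Gm9888 in both (0.69 and 0.82). Transcription running on from Trim71 into Ccr4 may account for the rise: the deposited RPKM of Ccr4 was at most 0.476 of that of Trim71 in any of the 6 Trim71-/- libraries, as this needs. Activation of Ccr4 from its own start would also leave it below Trim71, and was not tested.

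Genes of the 2-cell-like state were higher with Tnrc6a in both genotypes. Reads moving among near-identical copies are argued against, because the summed counts, which this leaves alone, rose at least 21.1-fold. A rise of weakly expressed genes in general is argued against too, because the list's median exceeded all 10000 random lists matched on level (percentile 100 in both genotypes, 4.32 against a highest of 1.64 and 5.88 against 3.43). Tnrc6a itself may raise these genes, or the Tnrc6a population may hold more cells in this state for other reasons, since population and overexpression coincide. Neither was tested.

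For the 4 comparisons of 3 against 3 libraries, only 10 splits exist, which is too few for a share under 0.05. In each, 1 split, the real one, gave as many genes: 7403, 8005, 13007 and 12884, against a highest of 0 in the other splits.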

How the results depend on the processing

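The tests without chromosome 8 genes, the lists with single libraries left out and the matched seed background were chosen after the data were seen, and the other settings were planned. Of 85 repeated counts of called genes, 80 stayed within 1.5 times the reported count. The 5 that did not are those with a 2-fold minimum: 1077 and 1157 genes for Trim71-/- with Cas9 and with Tnrc6a, 2911 and 2954 for Tnrc6a in control and in Trim71-/- cells, and 179 for the interaction, by that setting's own construction. Of 7245 repeated tests of named genes, 7029 kept their call, 197 no longer passed, 19 newly passed and 0 reversed. Of 1232 repeated list tests, 1185 were unchanged, 35 no longer passed and 12 newly passed. For genes and lists alike, a change of sign was counted as unchanged where neither test passed. With an estimated correlation, 5 lists passed in place of 10 (Trim71-/- with Cas9), 5 in place of 11 (Trim71-/- with Tnrc6a) and 5 in place of 11 (Tnrc6a in Trim71-/- cells). Seed sets passing with Tnrc6a were 0 in control cells and 1 with 8mer sites. In Trim71-/- cells they were 1, then 2 with 8mer sites, 0 with an estimated correlation and 0 against the matched background. The cause was not tested.

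The median interaction of genes higher in Trim71-/- cells (0.0247) turned to -0.000900 with relative log expression factors and ranged from -0.0148 to 0.0301 with single libraries left out. That of the lower genes (0.0346) ranged from -0.00891 to 0.0499. Both were negative without Tnrc6a control replicate 1 or 2 or Tnrc6a Trim71-/- replicate 2. In these settings the median interaction of all tested genes turned too, from 0.0213 to -0.0142, -0.0158 and -0.0174. With relative log expression factors and all 12 libraries it was -0.00505, so a change of scaling factors alone was enough to turn it. The turn was thus one of genes at large rather than of these sets. Whether scaling also made the turn with single libraries left out was not tested. Counts of called genes with single libraries left out ranged from 6417 to 7000 and from 6955 to 7110 for Trim71-/-, from 12094 to 12430 and from 12098 to 12348 for Tnrc6a, and from 1059 to 1403 for the interaction. The positive share of interaction genes was 67.5% here, 55.6% with relative log expression factors, 55.4% in DESeq2, and 51.7%, 51.1% and 52.9% without Tnrc6a control replicate 1, 2 or Tnrc6a Trim71-/- replicate 2.

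Replicate numbers do not pair the libraries: over 18 pairs of same-numbered libraries of different groups, correlations of residuals ran from -0.127 to 0.0509, with 0 over 0.1. A block for the number gave 7266, 7851, 12901, 12789 and 1335 genes in the order above. It gave 9, 10, 9, 10 and 6 lists, shared counts of 2395 and 2343 for Trim71-/- and of 5169 and 5402 for Tnrc6a, and size medians of 0.0235 and 0.0342. Small changes were often missed in the simulation, where 48% of genes with the smallest change were called. Far more genes passed in the data than were changed there, so this share need not hold for the data.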

Other observations

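Which tests were planned differs here: the seed test was planned, its matched background was chosen only after the results were seen.

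Egr1, an immediate early gene induced by growth factor signalling, was high in 1 group alone. It stood at 73.88 CPM in the Cas9 control group and at 18.08, 19.78 and 17.39 CPM in the Cas9 Trim71-/-, Tnrc6a control and Tnrc6a Trim71-/- groups (n = 3 each). Igf2, an imprinted growth factor gene, was also high in 1 group alone, with 26.9 CPM in the Tnrc6a control group and 7.74, 6.10 and 8.88 CPM in the Cas9 control, Cas9 Trim71-/- and Tnrc6a Trim71-/- groups. Hand1, of the trophoblast list, stood at 10.24 CPM in the Tnrc6a control group and at 2.23 CPM or less in the others, though its interaction did not pass (edgeR adjusted p = 0.0879). Mest, an imprinted gene, instead followed mainly the genotype, at 55.12 and 43.03 CPM in the control groups and 111.3 and 82.99 CPM in the Trim71-/- groups. These genes were chosen from the lists after their values were seen.

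A hypothesis was that overexpressed Tnrc6a changes repression through the seed shared by miR-290 and miR-302. Against a background matched on 3' UTR length and GC content, genes with these matches were higher with Tnrc6a by 0.0587 in Trim71-/- and 0.0658 in control cells. The largest absolute difference of a family that stem cells lack was 0.0431 (miR-122). Genes with miR-17, miR-20 and miR-106 matches were higher by more (0.0677 and 0.0725 in the same order), and those with let-7 matches by less (0.00181 and 0.0345). The shift was thus not largest for the miR-290 and miR-302 seed. A gene with matches of several families counted in each of their sets, so the ranking does not tell these seeds apart. Neither genotype passed camera with the matched background, so the data leave this open. Small shifts of this size may also come from 3' UTR features that the matching did not cover, which was not tested.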
